A study of Homo sapiens with 4 samples.

How the data were processed

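RNA was measured in 4 samples of the MOLM-13 line, 1 library each, titled Control, D2, D3 and D5. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. Per the submitters' processing notes the tools were HISAT2 2.1.0 and HTSeq 0.6.1 with the genome build GRCh38. Whether counting used strand is not given in the sources used here, so genes that overlap another gene or have an antisense partner are uncertain, and for named genes with 20% or more of their exonic bases in exons of another gene the share is given. The deposited files hold whole-number counts per gene, not normalized. The authors also deposited FPKM values, which equal the count divided by a fixed length per gene and by the library's total count. 5 genes have FPKM values below 0 in at least 1 library and were left out wherever FPKM was used.

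The 50470 gene identifiers were matched to current symbols, with 35275 matched to a name, and 50137 to the GENCODE annotation of GRCh38 for gene type, position and exonic length. Groups were taken from the titles, and the source name places D2, D3 and D5 together as POLR2A knockout. The libraries held 45005062 counts (Control), 46914776 (D2), 43982381 (D3) and 47519029 (D5), with TMM factors of 0.939, 1.00, 1.01 and 1.05. In these libraries 3 counts are 0.071, 0.0638, 0.0672 and 0.0602 CPM. Reads were not marked with molecular identifiers in any source used here, so intervals cover counting error only. Genes with 1 count or more numbered 20552, 21045, 21088 and 23135.

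Log2 ratios between 2 libraries are differences of log2 CPM (edgeR 4.0.16 in R 4.3.3, TMM, prior count 2) with an exact Clopper-Pearson conditional-binomial 95% interval of the 2 counts. The comparisons were D2, D3 and D5 each against Control, D3 against D2, D5 against D3 and D5 against D2, over 12520 genes with a mean CPM of at least 1. No p-value is given for them because there is 1 library per title. The same lists of D2, D3 and D5 share Control, so 100 draws of unchanged libraries were made with the real means, library sizes and dispersions. These dispersions include any difference between D2, D3 and D5. The only test was edgeR's quasi-likelihood test of D2, D3 and D5 as 1 group against Control, with Benjamini-Hochberg adjustment and 2 residual degrees of freedom. Nothing states whether the samples came from separate cultures, so these p-values measure only the spread between these samples.

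Gene lists were fixed before the data were examined. For each, the median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. A list needed 3 measured members. Transcripts of RNA polymerase III (1 of 15 matched, 0 measured) and small nuclear RNA genes (0 of 16 matched) could not be described, and erythroid and fibroblast markers had 0 measured members. Genes named in the text follow a rule fixed at the same time: polymerase II subunits; the 10 highest and 10 lowest protein-coding genes per comparison with Control at a mean CPM of at least 10 with an interval that excludes equality; the same for the smallest of the 3 ratios and for D5 against D2; the 3 highest and 3 lowest measured members of each list; the 10 lowest adjusted p in each direction; and 12 genes chosen for their role in this leukaemia or as controls. Lists of hypoxia-response genes and lysosomal genes were added after the data were examined, and genes named from them or from groups found in the data were chosen after their values were seen.

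The steps were tested on simulated data: in 10 runs, 200 of 12520 genes were changed by known folds. For 3 knockout libraries against Control the edgeR test called 86.6% of genes raised 4-fold, 13.0% of genes raised 2-fold, 17.4% of genes lowered to 0.5-fold and 72.4% of genes lowered to 0.25-fold, and 0.0706% of unchanged genes. The rule for D2 against Control found 96.0%, 44.8%, 51.4% and 97.2% of these genes, and 5.15% of unchanged genes. Of 100 lists of 30 unchanged genes, 6 lay outside the central 95% of random lists. Alternatives were DESeq2 1.42.0 size factors or library totals in place of TMM, other expression filters, a prior count of 0.5, the deposited FPKM values, DESeq2's Wald test, and leaving out D2, D3 or D5. Scaling by totals alone moved the median ratio of all genes by 0.09 in D2, 0.11 in D3 and 0.16 in D5 against Control, and reported ratios are relative to the TMM scale. Figures were drawn with matplotlib 3.10.9.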

Results

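MOLM-13 is a human acute myeloid leukaemia cell line that carries the KMT2A-MLLT3 fusion. In this study MOLM-13 cells with an inducible Cas9 nuclease received a lentivirus with a guide RNA against POLR2A, the gene of the largest subunit of RNA polymerase II, or a control lentivirus, and their RNA was sequenced to learn why these cells depend on POLR2A. There were 4 libraries: Control, and D2, D3 and D5, which the labels group as POLR2A knockout without saying what sets D2, D3 and D5 apart. The total count was 45005062 in Control, 46914776 in D2, 43982381 in D3 and 47519029 in D5, and 12520 of 50470 listed genes had a mean normalised read count of at least 1 CPM (counts scaled to library size) over the 4 libraries. Each title has 1 library and so no replicate. A difference between 2 libraries is given as a log2 ratio with an exact 95% interval that covers counting error only, and it compares those libraries, not the conditions. A gene counts as apart when it differs by 2-fold or more and the interval excludes equality. Rose and fell mean higher or lower than in Control, not a change followed over time.

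POLR2A itself (ENSG00000181222, GRCh38 chromosome 17, 7484366 to 7514616) was at 369 CPM in Control, 343 CPM in D2, 386 CPM in D3 and 300 CPM in D5. Its log2 ratio to Control was -0.10 in D2 (95% interval -0.14 to -0.07), 0.07 in D3 (0.04 to 0.10) and -0.30 in D5 (-0.33 to -0.26), and the mean of the 3 ratios was -0.11, or 0.009 when libraries were scaled by their totals alone. A count over the whole gene does not read small insertions or deletions made by Cas9, so it neither checks nor contradicts the labels. Of the 11 measured polymerase II subunits, 0 were apart from Control in D2 and in D3, and 2 were higher in D5, POLR2K (1.19) and POLR2L (1.12; 22.5% of its exonic bases lie in exons of another gene). POLR2F, the remaining subunit, had 0 counts in Control, 0 in D2, 9 in D3 and 4 in D5 and was under the filter. The 48 measured initiation and elongation factors of polymerase II had median log2 ratios of 0.11 in D2, 0.04 in D3 and 0.04 in D5. HEXIM1, an inhibitor of the elongation kinase P-TEFb, was higher by 1.11 in D3 and RPAP1, which helps to assemble polymerase II, was at -1.31 in D5. The 57 tested genes within 1 Mb of POLR2A had median ratios of -0.10, -0.25 and -0.13. Among the 15 measured members of the fixed list of close neighbours, ACAP1 (log2 fold change -4.16, SE 0.25, adjusted p = 0.000287, edgeR quasi-likelihood test) and NLGN2 (-2.37, SE 0.41, adjusted p = 0.0208) fell in the 3 libraries together, and the list medians were -0.27, -0.39 and -0.57. In that list 1 rose and 3 fell without D2, and 3 fell without D5.

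D2 was compared with Control to ask which transcripts differ with the POLR2A guide in the library titled D2. The lowest genes were close to absent in D2: the netrin receptor gene UNC5B had 1902 counts in Control and 1 in D2 (log2 -9.44, 95% interval -16.35 to -8.57). The retinaldehyde dehydrogenase gene ALDH1A3 had 1834 and 3 (-8.66, -11.69 to -7.86), and 28.6% of its exonic bases lie in exons of another gene. FADS2, which encodes the delta-6 desaturase of polyunsaturated fatty acids, was at -5.24 (-5.40 to -5.10). UNC5B, ALDH1A3 and FADS2 belong to the genes, described below, that were close to absent in D2, D3 and D5 alike. No library shows the knockout cells before POLR2A was targeted, so a loss of these transcripts is not shown. Among protein-coding genes with a mean CPM of at least 10, NAV3 was highest at 4.86 (4.63 to 5.14). MARCO, a scavenger receptor gene of macrophages, was at 3.70 (3.24 to 4.38). By comparison, the list of monocyte and macrophage genes had a median of -0.13, with 3 of 30 members higher and 5 lower. In all, 1383 genes were apart, 481 higher and 902 lower in D2. Simulated unchanged libraries with the spread seen among D2, D3 and D5 gave a mean of 652 (highest of 100 draws, 716).

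Among the gene lists, cholesterol synthesis was lowest in D2, with a median log2 ratio of -0.90 and 9 of 24 measured members lower, 0 higher and 15 neither. Glycolysis genes followed at -0.65, with 9 of 25 lower. That fixed list also holds hypoxia-response genes that are not glycolytic enzymes, such as BNIP3, CA9, VEGFA and ANKRD37. KMT2A-MLLT3 programme genes were at -0.44, with 4 of 25 lower, and S phase genes at -0.40, with 2 of 36 lower. All 4 medians lay below each of 10000 random lists matched on expression. Replication-dependent histone genes had a median of 1.19, with 7 of 12 higher. Unfolded protein response genes were at 0.36 and nuclear-encoded oxidative phosphorylation genes at 0.28. These last 3 medians lay above each random list.

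**Figure D1:**
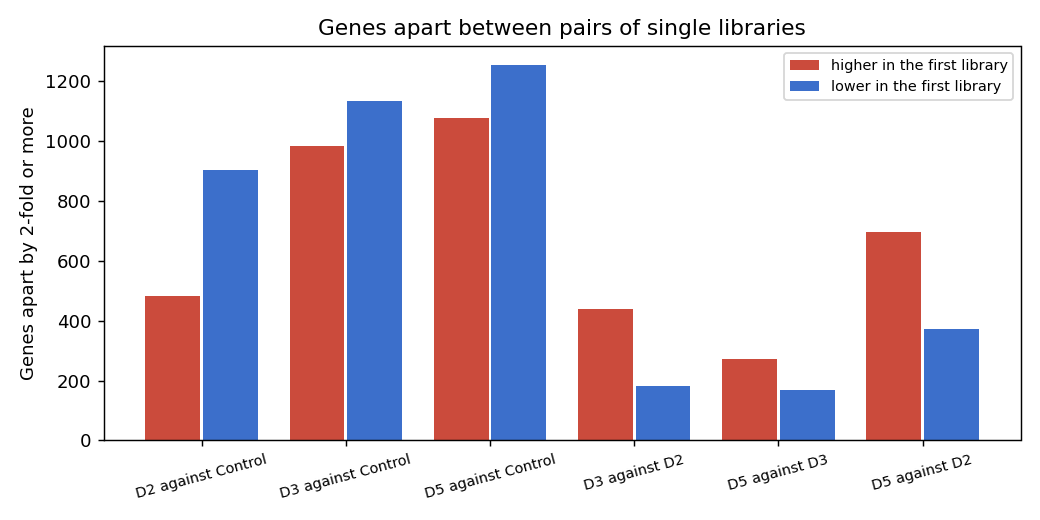
Number of genes apart by 2-fold or more between pairs of single libraries (y axis), higher (red) or lower (blue) in the library named first; each bar is a count over 12520 tested genes. The comparisons with Control hold 1383, 2116 and 2332 genes, and those between knockout libraries 621, 442 and 1066.

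D3 was compared with Control in the same way, and proliferation genes stood out. S phase genes had a median log2 ratio of -1.07 with 22 of 36 members lower, and mitosis genes -0.97 with 18 of 36 lower. The replication licensing factor gene CDT1 was at -2.15 and the ribonucleotide reductase gene RRM2 at -2.06. Monocyte and macrophage genes went the other way, with a median of 0.48 and 13 of 30 members higher and 0 lower. CYBB, the catalytic subunit of the phagocyte NADPH oxidase, was at 5.58 (95% interval 5.11 to 6.34), and LYZ, the gene of lysozyme, at 3.29 (3.25 to 3.33), although 34.0% of LYZ's exonic bases lie in exons of another gene. Genes apart numbered 2116, of which 982 were higher and 1134 lower in D3, or 1192 and 946 when libraries were scaled by their totals alone. Simulated unchanged libraries gave a mean of 656.

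MYC and nucleolar target genes had a median of -0.53 in D3, with 4 of 42 members lower and 38 neither, against 0.002 in D2. Integrated stress response genes were at -0.59 (4 higher, 8 lower, 15 neither), immediate early and short-lived transcripts at -0.55 (4 higher, 10 lower, 28 neither) and spliceosome genes at -0.35 (1 higher, 3 lower, 36 neither). EGR1, an immediate early transcription factor gene, was at -3.95. Replication-dependent histone genes were at 2.32, with 11 of 12 higher. Mitochondrially encoded mRNAs were at 0.50 with 0 of 13 members apart.

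D5 was compared with Control last and held the most genes apart of the 3 comparisons. Cholesterol synthesis genes had a median log2 ratio of -1.42, with 17 of 24 lower, S phase genes -1.22, with 23 of 36 lower, glycolysis genes -1.05, with 13 of 25 lower, and 18 of 36 mitosis genes were lower. LSP1, a leukocyte actin-binding protein gene, was at -7.16 (95% interval -8.29 to -6.60) and FADS1, the delta-5 desaturase gene next to FADS2, at -6.00 (-6.52 to -5.65). BCL2, an antiapoptotic gene, was at -2.13 (-2.22 to -2.04), and its relative BCL2A1 was at 4.25 (3.88 to 4.76). SEMA6B, a semaphorin gene, was at 3.35 (3.17 to 3.55) in D5, against -0.94 in D2. The 2332 genes apart split into 1077 higher and 1255 lower, or 1416 and 969 when libraries were scaled by their totals alone.

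DNA damage and repair genes had a median of -0.67 in D5, with 1 higher and 6 lower of 28, and subunits specific to RNA polymerases I and III had -0.54, with 2 of 18 lower. The lists of monocyte and macrophage genes (0.59, 12 of 30 higher) and replication-dependent histones (2.20, 11 of 12 higher) lay above each of 10000 random lists. Short genes were higher in D5 as a class: outside ribosomal, mitochondrial and histone genes, those under 1000 exonic bases had a median D5 to D3 ratio 0.28 above that of genes with 4000 or more. This stands beside the D5 values of ribosomal protein and oxidative phosphorylation genes. Histone genes differed little between D5 and D3 (median -0.05, 0 of 12 apart). Cytosolic ribosomal protein genes were at -0.25 in D2, -0.20 in D3 and -0.08 in D5, or 0.08 in D5 when scaled by totals.

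**Figure D2:**
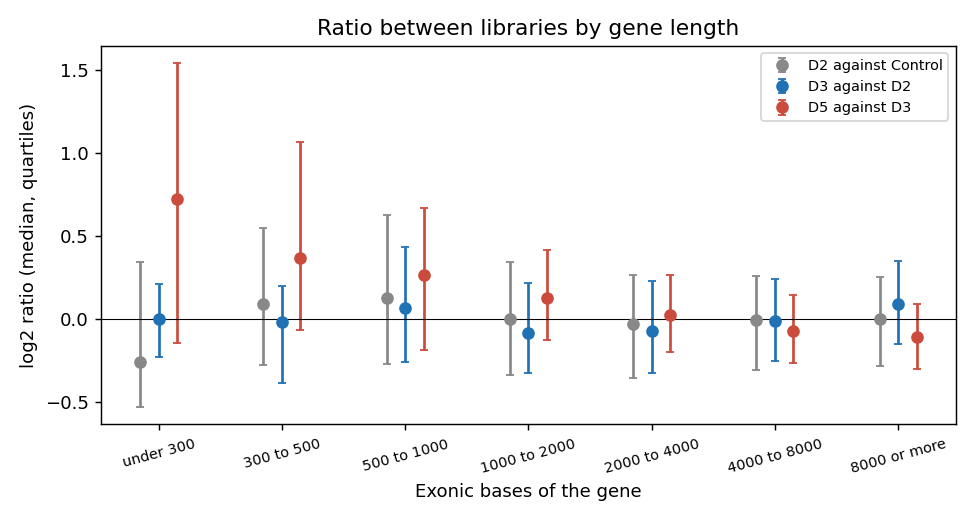
Median log2 ratio between libraries (y axis) by the number of exonic bases of the gene (x axis), with bars from the lower to the upper quartile of genes. For D5 against D3 the median runs from 0.72 in genes under 300 bases to -0.11 in genes of 8000 or more.

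The 3 comparisons with Control were then set side by side. UNC5B, ALDH1A3, FADS2, RASD1 and LSP1 were among the lowest in each, and NAV3, RENBP, CYBB, MARCO and BCL2A1 among the highest. In D2, D3 and D5 alike, 925 genes were apart in the same direction, 368 higher and 557 lower. Unchanged simulated libraries that share a control gave a mean of 86 such genes (highest 113), with a spread taken from D2, D3 and D5. Independent lists would share 3.25 higher and 8.19 lower genes, but these lists share Control, so that is no yardstick for them. Without D2 the count was 1594. Across genes, which are not independent replicates, the covariance of log2 ratios was 0.709 for D2 and D3, 0.652 for D2 and D5 and 0.882 for D3 and D5, against 0.128 in simulation for each pair, and the correlations were 0.868, 0.790 and 0.898 against at most 0.519, 0.517 and 0.527. With a single control library that cannot be split, part or all of the excess may come from that shared control.

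A test across the 3 knockout libraries as one group against Control asked which genes differ beyond the spread among D2, D3 and D5. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 99 genes rose and 383 fell at an adjusted p below 0.05. FADS2 fell most clearly (log2 fold change -5.30, SE 0.22, adjusted p = 6.71e-05), followed by ALDH1A3 (1834 counts in Control against 3, 1 and 5, adjusted p = 7.51e-05) and UNC5B (1902 against 1, 1 and 5, adjusted p = 8.35e-05). RASD1, a Ras-related gene induced by glucocorticoids, and MYO7A, an unconventional myosin gene, also fell. RETN, which encodes resistin, rose from 11 counts in Control to 371, 561 and 409 (5.18, SE 0.58, adjusted p = 0.00307), and FCAR, the IgA Fc receptor gene, from 1 count to 290, 527 and 282. TREM2, a receptor gene of macrophages and microglia (3.37, SE 0.50, adjusted p = 0.011), CELSR3 and PPIC rose as well. The lone Control was assumed to vary like the other libraries, with 2 residual degrees of freedom, and the spread includes whatever sets D2, D3 and D5 apart. Of the 482 genes, 364 were called without D3; H2BC4, HERPUD1, IFITM1 and SRGN, named in the groups that follow, were not. The number of called genes was 2322 without D2 (963 up, 1359 down), 413 without D3 (93 up, 320 down) and 794 without D5 (235 up, 559 down), 1142 by DESeq2's Wald test (492 up, 650 down) and 1825 with no expression filter (659 up, 1166 down).

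**Figure D3:**
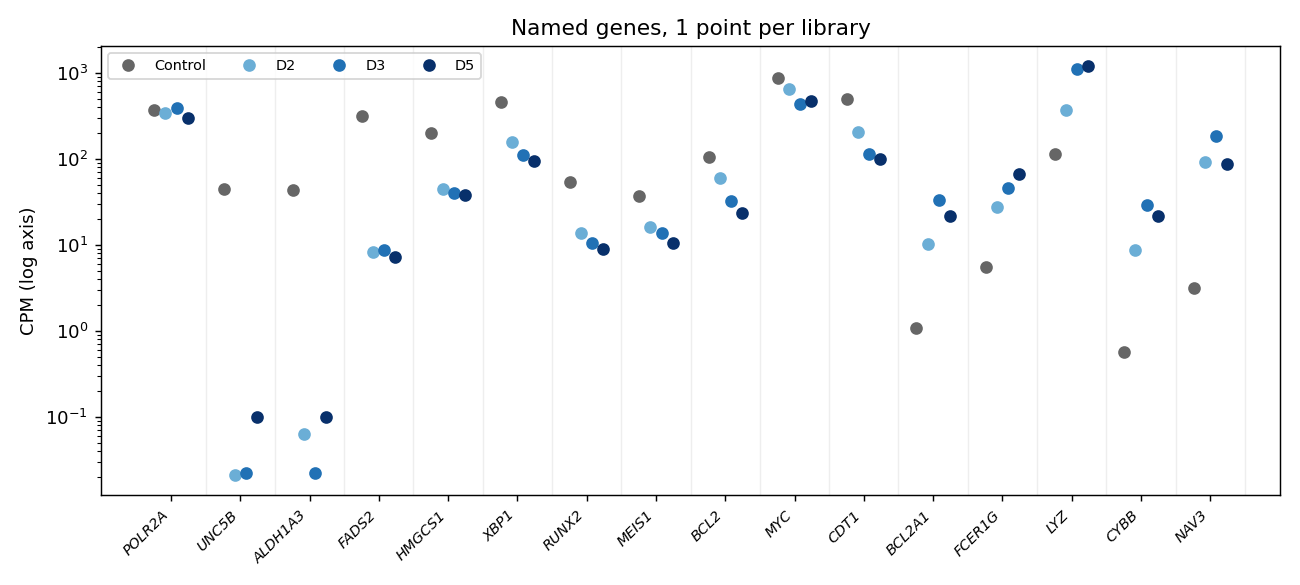
CPM (y axis, log scale) of 16 named genes, with 1 point per library and no error bars. NAV3 had 3.15 CPM in Control and 92.5 CPM in D2; POLR2A lay between 300 CPM and 386 CPM in the 4 libraries.

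Genes tied to the KMT2A-MLLT3 fusion were lower in each knockout library, with medians of -0.44, -0.58 and -0.58. In the test of 3 libraries against Control, 3 of 25 measured members fell over all genes and 9 fell adjusted over the list alone, with 0 rising in either count; 10 fell over all genes without D2 and 7 without D5. RUNX2, a Runt-domain transcription factor gene, fell by 2.29 (SE 0.27, adjusted p = 0.00386) and MEIS1, a cofactor of HOXA9, by 1.44 (SE 0.29, adjusted p = 0.0321). BCL2 was at -1.42 (SE 0.42, adjusted p = 0.113) and FLT3, a receptor tyrosine kinase gene, at -0.91 (SE 0.21, adjusted p = 0.0581), which did not pass. HOXA9, MYB and CDK6 were at -0.20, 0.03 and 0.06 (adjusted p = 0.723, 0.972 and 0.925), and 27.0% of the exonic bases of HOXA9 lie in exons of another gene. Among the 17 measured BCL2 family genes BCL2A1 rose (4.31, SE 0.73, adjusted p = 0.0188), and MCL1 was at -0.23 (adjusted p = 0.659). In that list 2 also fell by DESeq2, 2 without D2 and 1 without D5.

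Cholesterol synthesis genes and the glycolysis list, which holds some hypoxia-response genes, were lower in each knockout library. Of 24 measured cholesterol synthesis genes, 8 fell over all genes and 17 adjusted over the list alone, with 0 rising; 16 fell over all genes without D2 and 13 without D5. HMGCS1, the cytosolic HMG-CoA synthase gene, fell by 2.29 (SE 0.21, adjusted p = 0.00127), and INSIG1, a sterol-regulated brake on the pathway, by 1.97 (SE 0.35, adjusted p = 0.0231). The median moved from -0.90 in D2 and in D3 to -1.42 in D5. Glycolysis genes showed 8 of 25 members falling over all genes and 14 adjusted over the list alone, and over all genes 13 without D2 and 12 without D5. PFKFB4, which sets the level of a glycolytic activator, fell by 3.77 (SE 0.28, adjusted p = 0.000553), the neuronal enolase gene ENO2 by 4.29 (SE 0.53, adjusted p = 0.00449) and the hexokinase gene HK1 by 3.35 (SE 0.52, adjusted p = 0.0127). GAPDH, often used as a control gene, was at -0.49, -0.67 and -1.05 and ACTB at -0.26, -0.77 and -1.42. Mitochondrially encoded mRNAs (medians 0.25, 0.50 and 0.41) and nuclear-encoded oxidative phosphorylation genes (0.28, 0.22 and 0.33) had 0 members called by edgeR over all genes, 0 adjusted over the list alone and 0 by DESeq2, with 1 and 3 members at an unadjusted p below 0.05. Without D2, 1 and 2 members rose. In D5 the mitochondrial genes MT-ND3 (1.78) and MT-ATP8 (-3.06; 22.2% of its exonic bases lie in exons of another gene) lay far apart.

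S phase and mitosis genes had medians below 0 in all 3 libraries, though in D2 mitosis genes were at -0.25 with 0 of 36 apart. MYC and nucleolar target genes were at 0.002 in D2. How many genes of these lists passed the test depended on whether D2 was included. Of 36 S phase genes 1 fell over all genes and 10 adjusted over the list alone, and 31 fell over all genes without D2, 2 without D3 and 4 without D5. CDT1 fell by 1.85 (SE 0.36, adjusted p = 0.0321). Of 36 mitosis genes and of 42 MYC and nucleolar target genes 0 passed in either count, with 11 and 5 at an unadjusted p below 0.05 in the same edgeR fit and 3 and 2 falling by DESeq2. Without D2, 24 mitosis genes and 9 MYC and nucleolar target genes fell, and 0 and 2 without D5. MYC was at -0.76 (SE 0.28, adjusted p = 0.187). Among the 28 DNA damage and repair genes, LIG4, the ligase gene of end joining, rose (1.82, SE 0.37, adjusted p = 0.0365), and 2 rose and 11 fell without D2. Of 12 measured replication-dependent histone genes 3 rose over all genes and 7 adjusted over the list alone, and over all genes 10 rose without D2, 2 without D3 and 5 without D5. H2BC4 rose by 2.89 (SE 0.61, adjusted p = 0.0412) and H4C9 by 2.94 (SE 0.65, adjusted p = 0.0481). Only 12 of the 38 matched histone genes passed the filter, so these counts and the list medians cover a part of the list. Histone genes of 1 class share near-identical sequence, so the values of single genes are uncertain. Whether RNA was selected by its poly(A) tail is not stated here, so a rise in total histone RNA is not shown.

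Some genes of monocytes and macrophages rose, while members of the progenitor list went both ways. In the list of monocyte and macrophage genes the median log2 ratio was -0.13 in D2, 0.48 in D3 and 0.59 in D5. Of 30 measured members, 3 were higher by 2-fold or more in D2, 13 in D3 and 12 in D5. In D2 5 members were lower, and 0 in D3 and in D5. FCER1G, the common Fc receptor gamma chain gene, rose by 3.06 (SE 0.52, adjusted p = 0.0192). NCF1, which has near-identical pseudogenes, was at -1.60 in D2 and -0.20 in D5. In the list of granule and progenitor genes 3 of 24 rose over all genes, and adjusted over the list alone 5 rose and 2 fell. Over all genes 5 rose and 3 fell without D2, 2 rose without D3, and 4 rose and 1 fell without D5. CEBPE, a transcription factor gene of granulocyte maturation, rose by 2.13 (SE 0.37, adjusted p = 0.0194), and SRGN, the granule proteoglycan gene, by 1.48 (SE 0.26, adjusted p = 0.0225). The granule protease and peroxidase genes CTSG and MPO were at -0.99 and -1.10 (adjusted p = 0.108 and 0.159).

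XBP1 fell by 1.92 (SE 0.28, adjusted p = 0.0107) and HERPUD1 by 1.06 (SE 0.23, adjusted p = 0.0423), the called members of the 24 unfolded protein response genes, whose list median was above 0 in each library; 4 rose and 3 fell without D2, 1 fell without D3, and 1 rose and 3 fell without D5. In the integrated stress response list 2 of 27 fell, DDIT4 (-1.94, SE 0.29, adjusted p = 0.0111; 41.2% of its exonic bases lie in exons of another gene) and CBS (-2.31, SE 0.48, adjusted p = 0.04), and adjusted over the list alone 1 rose and 4 fell. Over all genes 2 rose and 12 fell without D2, 1 rose and 2 fell without D3, and 1 rose and 4 fell without D5. Of 21 measured inflammatory genes 3 fell over all genes, and adjusted over the list alone 1 rose and 3 fell. Over all genes 2 rose and 4 fell without D2, 2 fell without D3, and 1 rose and 3 fell without D5. TNF fell by 2.68 (SE 0.44, adjusted p = 0.0158) and its target TNFAIP3, an inhibitor of NF-kB signalling, by 1.26 (SE 0.22, adjusted p = 0.0192).

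Of 42 immediate early and short-lived transcripts 1 rose, CCND1 (2.48, SE 0.53, adjusted p = 0.0426), and 4 fell over all genes, while 3 rose and 9 fell adjusted over the list alone. Over all genes 5 rose and 12 fell without D2, and 2 rose and 6 fell without D5. Of 34 measured interferon-stimulated genes 2 fell over all genes, IRF7 (-1.50, SE 0.22, adjusted p = 0.0113) and IFITM1 (-2.45, SE 0.50, adjusted p = 0.0355; 32.5% of its exonic bases lie in exons of another gene), and adjusted over the list alone 2 rose and 2 fell. Over all genes 4 rose and 3 fell without D2, and 1 fell without D3. The median of 21 heat shock genes was 0.03, -0.07 and -0.12, and the values in D3 and D5 are smaller than the shift of all genes when scaled by totals (0.11 and 0.16), which turns their sign. Spliceosome genes, ribosomal protein genes, heat shock genes, polymerase II subunits, polymerase II factors and subunits of polymerases I and III each had 0 calls by edgeR over all genes and 0 adjusted over the list alone, with 2, 1, 1, 1, 5 and 2 members at an unadjusted p below 0.05 and 1, 0, 0, 1, 1 and 0 members called by DESeq2. Without D2, 3 polymerase II factors and 3 subunits of polymerases I and III fell, and 2 factors and 1 polymerase II subunit rose. In the same fit 1 spliceosome gene rose and 2 fell, and 1 heat shock gene fell; without D5, 1 spliceosome gene fell.

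**Figure D4:**
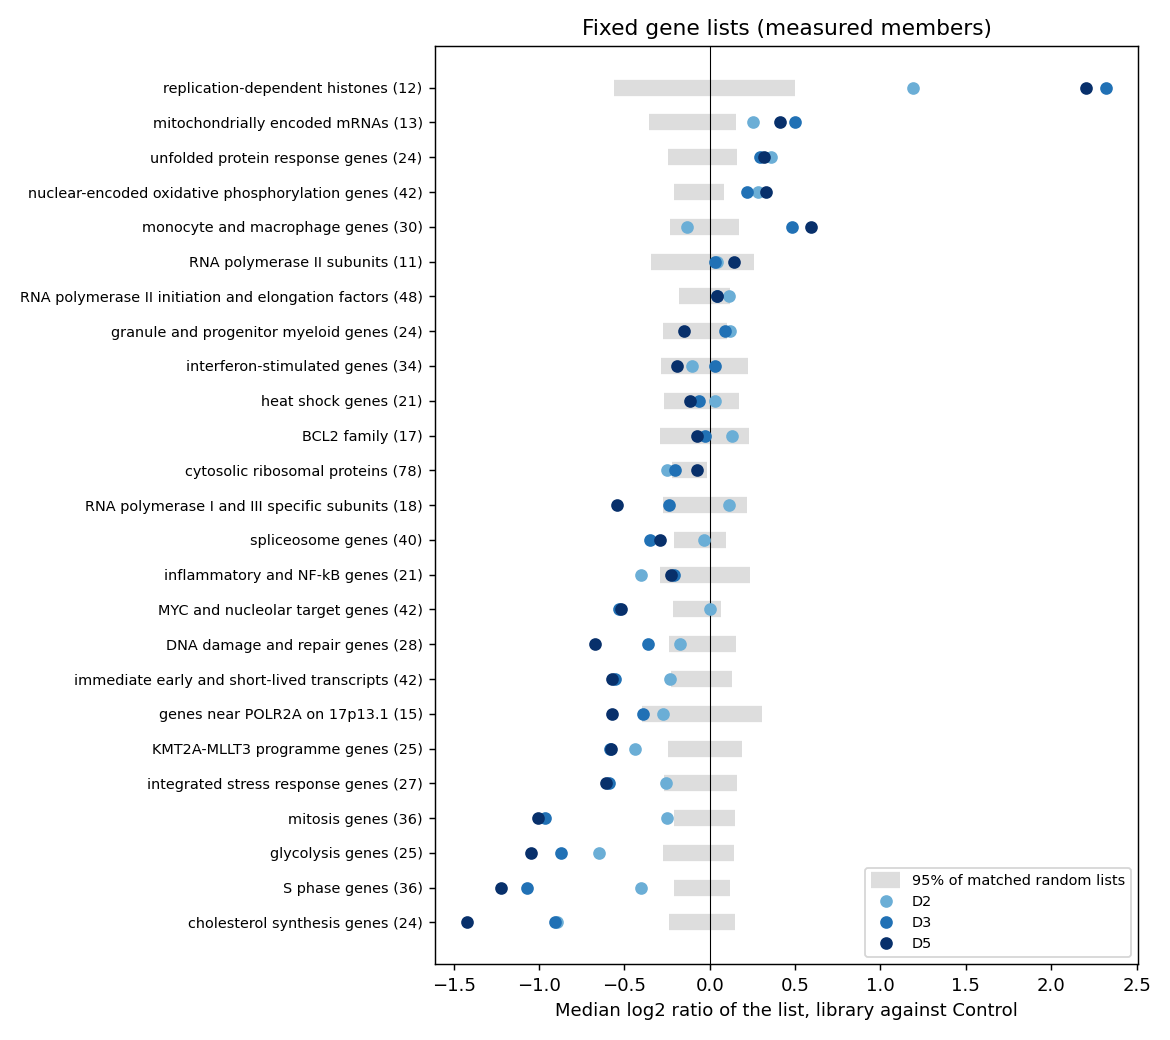
Median log2 ratio against Control (x axis) of the measured members of fixed gene lists (rows, number of members in brackets) in D2, D3 and D5 (points); grey bars span 95% of matched random lists for the mean of the 3 ratios. A point outside a bar can lie within 95% of the random lists of its own library, as for spliceosome genes in D5 (-0.29). Cholesterol synthesis genes lie lowest in D5 at -1.42 and replication-dependent histones highest in D3 at 2.32.

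The knockout libraries were last compared with each other, which leaves Control out. Members are counted here by the sign of the log2 ratio alone, and the number apart by 2-fold or more is given beside it. S phase genes were below 0 in D3 against D2 for 36 of 36 members (median -0.72, 0 apart). Mitosis genes were likewise below 0 for 36 of 36 (-0.62, 3 apart), while D5 lay close to D3 for both lists (-0.14 and -0.07). MYC and nucleolar target genes were also below 0 in D3 against D2 for 42 of 42 members (-0.51, 0 apart). Monocyte and macrophage genes were above 0 in D3 against D2 for 27 of 30 members (0.64, 10 apart). Cholesterol synthesis genes were below 0 in D5 against D3 for 23 of 24 (-0.53, 2 apart). D3 against D2 held 621 genes apart, D5 against D3 held 442 and D5 against D2 held 1066, against means of 655, 649 and 649 in simulated unchanged libraries whose spread was taken from these same 3 libraries. Higher in D5 than in D2 were SEMA6B (4.29, 95% interval 4.06 to 4.55), the costimulatory receptor gene CD86 (2.84, 2.60 to 3.13) and UBALD2 (2.14, 2.09 to 2.19). Lower were MT-ATP8 at -3.61, EGR1 at -2.11 (-2.21 to -2.01) and SLC38A1, a glutamine transporter gene, at -2.10.

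Markers of other cell types were mostly near or under the filter. Summed over each list, fibroblast markers were at 3.74 CPM in Control and at most 1.19 CPM in the others, and erythroid markers were under 1 CPM in each library. In the order Control, D2, D3 and D5, B cell markers summed to 65.3, 41.4, 25.4 and 19.0 CPM, of which PAX5 gave 60.7 CPM in Control, and epithelial markers to 30.3, 18, 12.2 and 14.7 CPM. T and NK cell markers summed to 109, 86.0, 113 and 52.6 CPM, with NKG7 at 93.3 CPM in Control, and megakaryocyte markers to 7.12 CPM in Control and 15.7 CPM in D5, with D2 and D3 in between. GP1BA, a platelet glycoprotein gene, rose (2.78, SE 0.47, adjusted p = 0.0179), and TRAC, the T cell receptor alpha constant gene, fell by 2.86 (SE 0.52, adjusted p = 0.0235).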

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

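The tests on the groups of genes described here were chosen after their values were seen. CD86, which encodes a costimulatory receptor of antigen-presenting cells, was apart from Control in opposite directions, lower in D2 (log2 ratio -1.02) and higher in D5 (1.82), with 2.84 between D5 and D2. It is a single library on each side and the difference was not tested. Beyond the genes named by rule, 8 other genes showed opposite directions in D2 and D5, among them the immediate early gene EGR3 (1.17 and -1.83) and the galectin gene LGALS2 (-1.19 and 2.24).

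Some genes were present in Control and close to absent in D2, D3 and D5 alike: 52 genes had at least 2 CPM in Control and at most a 1/32 share of it in each other library, against 0 genes for each of D2, D3 and D5 taken as the lone library, and 3 genes (FCAR, SMAD1 and KCP) showed the reverse. They lie on 23 chromosomes with at most 6 on 1, and include IFT27 and ZDHHC21, named after their values were seen. Immediate early and short-lived transcripts were at -0.23 in D2, -0.55 in D3 and -0.57 in D5 on the TMM scale. The D2 value argues against a full stop of transcription, in which these transcripts would be lost first. A fall shared by all transcripts would not show on this scale, so it stays open. Other cells mixed into Control stay open: T and NK markers, mostly NKG7, stood at 0.972 of their highest level elsewhere, which would hide a small share, and fibroblast, epithelial and B cell markers were at 3.14, 1.68 and 1.58 times theirs, at lower levels. Reading D2, D3 and D5 as an order is an assumption, since the labels do not give one. Under it, a population that already differed from Control before D2 and a change that grows from D2 to D5 cannot be told apart. Of 67 genes this low in D3 and D5, 77.6% were this low in D2, between the 50% and 80% set as bounds. The 95% interval of 65.8% to 86.9% treats genes of the same libraries as independent, so it covers no spread between libraries. Of the same genes, 97% were already at most 1/8 of Control in D2. An effect of losing POLR2A itself also stays open.

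D5 differed from the other libraries in its short genes and in some genes with few reads, while over all genes it lay closest to D3. Genes under 1000 exonic bases had a D5 to D3 ratio 0.28 above genes of 4000 or more (95% bootstrap interval 0.23 to 0.37), with 0.00 for D3 against D2, which is consistent with a difference in how the D5 library was prepared or sequenced. T and NK genes with few reads had summed counts of 179, 160 and 208 in Control, D2 and D3 and 45 in D5, or 22% of the mean level of the others, so reads carried over into all libraries but D5 may account for such low counts, though CD8A (48, 0, 0 and 5 counts), ZAP70 (17, 42, 29 and 20) and GNLY (5, 17, 59 and 14) went otherwise. Yet D5 had the most genes with 1 count or more (23135, against 20552, 21045 and 21088 in Control, D2 and D3). It also had the most genes with exactly 1 count (3107, against 1935, 2095 and 2020). Carry-over that spared D5 would not by itself give these numbers. Short genes were also 0.22 higher than long ones in D2 against Control, so length is not only a matter of D5. No biological explanation of the length trend was tested.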

How the results depend on the processing

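With DESeq2 size factors, library totals alone or a prior count of 0.5, each count of genes apart stayed within 1.5 times its value, as did the number of gene lists (18 of 28; 17 to 19 over the alternatives, with inflammatory genes at the edge) outside the central 95% of random lists and the number of named genes with a mean ratio of 2-fold or more (115; 91 with FPKM). BCL2 family, heat shock, interferon-stimulated, granule, ribosomal protein (D5) and spliceosome (D2) medians changed sign under another scaling, each inside that range in the comparison where it did; the spliceosome list was outside it in the mean of the 3 ratios. Among called named genes 0 changed sign under another scaling or prior. List medians moved by more than their own standard error in 99 of 532 alternatives and named genes by more than their counting interval in 294 of 904. In the order D2, D3 and D5 against Control, D3 against D2, D5 against D3, D5 against D2 and the count common to all 3, the genes apart numbered 3776, 4869, 5147, 2421, 2105, 3000 and 1982 with no filter and 430, 919, 1027, 161, 89, 362 and 290 at a mean CPM of at least 10, since more or fewer genes were counted. With log2(FPKM + 1) and no interval they were 402, 868, 1055, 110, 142, 338 and 270, and with no FPKM filter 494, 1010, 1222, 131, 171, 377 and 334; a pseudocount of 0.1 gave 756 (D2), 354 (D3 against D2), 284 (D5 against D3), 695 (D5 against D2) and 525 (common). A pseudocount of 1 pulls low genes toward 0. The cause of the other differences was not tested.

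Leaving out 1 knockout library gave 999 to 1594 common genes, and 869 without genes under 1000 exonic bases, chosen after seeing the data. The edgeR test called 413 to 2322 genes, the highest without D2, and the 482 genes were among those called without D2 and without D5, while 364 were called without D3. DESeq2's Wald test called 1142 (476 shared) and no filter 1825. In D5 against Control the split of higher and lower genes was 1077 and 1255, and 1416 and 969 by totals. No paired analysis was possible because each title has 1 library.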

Other observations

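The list of lysosomal genes was added after the data were examined, with its test fixed before its values were seen; the tests on hypoxia-response and sterol genes and on the lone libraries were chosen after theirs were seen. Lysosomal genes were higher in the knockout libraries. Of 43 measured genes, 37 were above Control in D2, 38 in D3 and 37 in D5, with medians of 0.50, 1.14 and 1.00, above each of 10000 random lists. In the edgeR test of 3 libraries against Control, 2 rose and 1 fell over all genes, and 21 rose and 1 fell adjusted over the list alone. PSAP, the precursor of lysosomal saposins, was at 0.71, 1.99 and 1.52, and CD63 at 1.08, 2.13 and 1.85, while CTSH was at -1.82, -2.31 and -2.90. The hypothesis that lysosomal genes move with the macrophage genes named a median of at least 0.3 in D3 and D5, and the lower of the medians was 1.00. In D2 the lists parted, with lysosomal genes at 0.50 and monocyte and macrophage genes at -0.13. D3 exceeded D2 by 0.55, with 38 of 43 ratios above 0 and 7 genes higher by 2-fold or more, a comparison that leaves out Control.

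Hypoxia-response genes outside the glycolysis list were lower in the knockout libraries, with medians of -0.52, -0.58 and -0.38 over 21 measured genes. The glycolysis list holds hypoxia-response genes too, so the falls of these lists may not be separate observations. P4HA1, a collagen prolyl hydroxylase subunit gene, was at -1.97, -2.24 and -2.14, and NDRG1 at -2.52, -1.40 and -1.81. A difference that sits in Control, such as oxygen or cell density at harvest, would leave D2, D3 and D5 alike. The median was 0.10 for D5 against D2 and 0.24 for D3 against D2, which leaves it open. For cholesterol synthesis genes the medians were -0.47 for D5 against D2 and -0.06 for D3 against D2, so a difference in Control stays open there too, as D5 is a single library. An effect of POLR2A loss on either list also stays open.

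The 482 genes called with Control as the lone library were set against fits with each other library alone. These called 0 genes by edgeR, with 106 genes (D2), 65 (D3) and 424 (D5) at an unadjusted p below 0.05, against 2463 for Control; with Control alone and 1 knockout library left out, 2322 (without D2), 413 (without D3) and 794 (without D5) genes were called. In the fits with D2, D3 or D5 alone, Control sat inside the group of the other libraries. Their common dispersions were 0.141 (D2), 0.136 (D3) and 0.123 (D5), against 0.0535 with Control alone. That wider spread leaves few genes to call, so these fits are no measure of chance. With 4 such splits, 1 of which gave as many genes, a share below 0.05 cannot be reached. The number of splits is also too small to judge chance.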
